A study of Mus musculus with 12 samples.

How the data were processed

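Pro-B cells of WT and Mettl14 KO mice were profiled by m6A-seq and by YTHDF2 RIP-seq. In m6A-seq, per the labels' protocols, polyadenylated RNA was broken to about 200 nt by sonication, m6A fragments were enriched with an antibody kit, and stranded libraries were made from enriched and input RNA. In RIP-seq, per the labels, RNA was recovered with an antibody to YTHDF2. The labels repeat the m6A protocol for the RIP samples, so details of the RIP lysis and washing are not given in the sources used here.

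Per the submitters' processing notes, the tools were CASAVA, Trim Galore, HISAT2 2.1.0, deepTools 2.0, Cufflinks and featureCounts, on genome build mm9. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, so genes with near-identical copies (ribosomal protein, histone and Zfp families) and overlapping antisense genes are uncertain. The authors deposited a table of raw read counts for 24507 gene symbols in 6 RIP-seq libraries. They also deposited a table of FPKM values for 16179 genes in the same libraries, per the file headers, and the rule for the genes listed is not given. The FPKM sums differ between libraries, as FPKM values do when the length of expressed transcripts differs. For m6A, the authors deposited 1 peak list per genotype from exomePeak, per the file headers, with a p-value for each peak. The deposited lists also give each peak's fold enrichment of immunoprecipitate over input, which is the peak caller's own ratio. It depends on how each list was made, so values of the 2 lists are set side by side without a test. Per the labels, the KO m6A sample was a pool from 3 mice; whether the WT list pools its 2 replicates, and the threshold on peaks, are not given in the sources used here. Some gene names in the lists had been changed to numbers by a spreadsheet (9 peaks per list), and those peaks were kept for overlaps by position but not matched to genes. Of the WT peaks, 8954 matched the count table by symbol and 139 by an older symbol, and 46 matched none; in KO these were 5000, 60 and 14.

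The inputs in the RIP tables carry names that could also describe the m6A inputs. They were taken as the RIP inputs because the tables are those of the RIP experiment. Samples were grouped by genotype and fraction from their titles. All count rows name a gene, and no column of per-sample values was left out.

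Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with at least 10 counts in at least 2 of the 6 libraries were kept (12810 genes), libraries were scaled by TMM, and CPM uses the TMM-scaled totals. A quasi-likelihood model with 4 groups (WT input, WT RIP, KO input, KO RIP) was fitted to all 6 libraries. The spread comes only from the WT pairs, with 2 residual degrees of freedom. edgeR's quasi-likelihood test was applied to WT RIP against WT input, to the KO minus WT difference in log2 RIP over input (an interaction term), and to KO input against WT input. The KO RIP against KO input ratio was taken from the fit as a value. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Of 24 gene lists, the 22 with at least 5 tested members were tested with camera, a competitive test against all other genes, at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. With an estimated correlation in its place, 0 of the lists called in each comparison passed (8, 8 and 9 lists with the preset value). That setting also draws on the 2 residual degrees of freedom, so p can rise without any inter-gene correlation. For m6A writers in WT RIP the estimate was −0.0075, below the preset value, yet camera p rose from 0.00524 to 0.101. Lists with estimates near or below the preset value are therefore not shown to owe their call to inter-gene correlation. In WT RIP, estimates lay well above the preset value for Zfp genes (0.47), ribosomal proteins (0.28), the respiratory chain (0.27) and cell cycle genes (0.22). Immediate early genes (0.16) and chromatin regulators (0.13) also lay above it. For such lists, p at the preset value may be too small. The same test was applied to the sets of genes with m6A peaks, again against all other genes, whether with peaks or without, while median differences of these sets are relative to genes without peaks. A test against genes without peaks alone was added after the results were seen. P-values of peak sets are unadjusted unless stated. The main tests, alternatives, gene lists and rule for naming genes were fixed before the data were examined.

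Named genes were the 10 with the largest and the 10 with the smallest log2 difference among those called, with a mean of at least 10 CPM and every library of one side beyond every library of the other. In the interaction, the KO ratio had to lie on one side of both WT ratios. Genes with Gm, LOC or terminal Rik names and immunoglobulin or T cell receptor variable segments were counted but not named. Up to 4 members per list with the smallest p, and 12 regulators chosen in advance, could be named besides. For peaks, the 10 WT and 5 KO peaks with the smallest p and no overlap in the other list were named, with ties going to the longer peak, in genes of at least 10 CPM in both inputs. Peaks were compared by an overlap of at least 1 bp of their spliced blocks on the same strand. Shares have Wilson 95% confidence intervals, which cover counting error only.

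The WT input replicates differed by 13.0 times the variance of counting (chi-square per degree of freedom) and the WT RIP replicates by 73.7 times, so each library was counted as its own sample. Their correlation across genes was 0.986 for inputs and 0.943 for RIPs. A length in kb was implied for 10271 genes from the ratio of input counts to FPKM, since no annotation was used.

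The steps were tested on simulated counts for the 12810 genes with 200 changed genes. In WT RIP against input, 17.9% of genes changed by 1 on the log2 scale, 64.2% of those changed by 2 and 89.4% of those changed by 3 were called with the right sign. In the interaction these shares were 1.49%, 25.4% and 78.8%, and between inputs 7.46%, 77.6% and 83.3%. Of unchanged genes, 0.0317%, 0.0476% and 0.0714% were called in these comparisons. All simulated libraries started from WT input levels, with the same spread for a gene in every library and genes drawn independently. The wider spread of the RIP pair and effects peculiar to a single KO library were thus not simulated. These shares therefore do not give error rates of the calls in the data. The overlap step found all 2000 of 2000 simulated overlaps.

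Alternatives were RLE scaling, library totals alone, no count filter, at least 50 counts, the WT libraries alone, a test against a 1.5-fold change, DESeq2 1.42.0, limma on log2(FPKM + 1), a replicate block, and leaving out each WT library in turn. For lists and peak sets an estimated correlation was used, and for peaks the better-scoring part of each list, a larger overlap, overlap by gene name and a minimum of 10 CPM. Genes without peaks were matched to those with peaks in 20 bins of mean CPM over all libraries, RIP included, and, as a choice made after the data were seen, of implied length. Leaving out 351 genes found mainly in KO RIP was also chosen after the data were seen. Scripts for peaks and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.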

Results

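The series measured N6-methyladenosine (m6A), a methyl mark on mRNA, and the transcripts bound by YTHDF2 in mouse pro-B cells, the stage at which the immunoglobulin heavy chain locus is rearranged. YTHDF2 is a cytoplasmic protein that binds m6A and recruits the CCR4-NOT deadenylase to mRNA. Cells were wild type (WT) or carried a knockout (KO) of Mettl14, which encodes the partner of the methyltransferase METTL3 in the m6A writer complex. Cells positive for B220 were grown with IL-7 for 5 days, and CD19+ cells without CD2 or immunoglobulin light chain were sorted. The 12 samples formed 8 groups: 2 WT and 1 KO samples each of m6A immunoprecipitate, its input, YTHDF2 immunoprecipitate (RIP) and its input. The KO m6A sample was pooled from 3 mice. The RIP libraries held 20443092 and 20486331 counts in WT input, 16391427 and 27409733 in WT RIP, 25186966 in KO input and 25516229 in KO RIP. The m6A data were analysed as 1 peak list per genotype, and the depth behind them is unknown. Each KO group had no replicate, so tests that involve KO assume that its libraries vary as the WT ones do. The p-values measure only the spread between these libraries, which may be technical, because the labels do not say that the WT RIP replicates came from separate animals.

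Mettl14 itself was lower in both KO libraries than in any WT library. Its level was 73.6 and 87.9 CPM (counts scaled to library size) in the WT inputs, 48.2 and 57.0 CPM in the WT RIPs, 26.7 CPM in KO input and 10.3 CPM in KO RIP. The deleted part of the gene is not given in the sources used here, so the remaining KO reads may come from the rest of the transcript or from cells without complete deletion. The log2 difference between KO and WT input was −1.60 (SE 0.27), which narrowly missed the threshold (adjusted p = 0.0508, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mettl3 read 33.5 and 36.5 CPM in WT input and 20.6 CPM in KO input, a log2 difference of −0.77 that did not pass (edgeR adjusted p = 0.485).

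The first comparison asked which transcripts YTHDF2 was associated with in WT pro-B cells. Transcripts of Il7r, Cd79b and Ikzf1 were enriched in RIP, while other B cell transcripts such as Cd79a were depleted. Transcripts of ribosomal proteins and the respiratory chain were almost all depleted. Il7r, the IL-7 receptor chain that pro-B cells need for growth, rose from 41.2 ± 3.59 CPM in input to 336 ± 104 CPM in RIP (SD, n = 2; log2 3.03, SE 0.26, edgeR adjusted p = 1.87e-04). Cd79b, a signalling chain of the B cell receptor, rose from 483 ± 54.0 to 4065 ± 1047 CPM (log2 3.07), and Ikzf1, which encodes the lymphoid transcription factor Ikaros, rose from 434 ± 26.5 to 2814 ± 435 CPM (log2 2.70). Rpl32, a protein of the large ribosomal subunit, fell from 1053 ± 91.0 to 24.0 ± 3.37 CPM (log2 −5.46, SE 0.21, edgeR adjusted p = 1.37e-04). Of 12810 genes tested, 3702 were higher and 4231 lower in RIP than in input, and 3036 and 3607 of these differed by at least 2-fold.

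Among genes past the threshold, those with the largest increases chosen by the fixed rule were Zfp87 (log2 4.02), Sertad3 (3.92), Trib1 (3.82), Tnfaip8l1 (3.73), Rgag4 (3.71), Rnf219 (3.69), Zfp52 (3.61), Zfp607a (3.57), Tlr2 (3.53) and Plcl2 (3.52). Trib1 encodes a pseudokinase adaptor of protein degradation and Tlr2 a receptor for bacterial lipoproteins. Those with the largest decreases were Rpph1 (log2 −6.09), Ndufa3 (−5.82), Ndufb6 (−5.62), Dnajc17 (−5.60), Tmem208 (−5.55), Dnajc19 (−5.55), Rpl32 (−5.46), Atox1 (−5.45), BC028528 (−5.45) and Acadsb (−5.36). Rpph1 is the RNA component of RNase P, Ndufa3 and Ndufb6 are subunits of respiratory complex I, and Atox1 is a copper chaperone.

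Transcripts of the m6A machinery differed in RIP. Ythdf1 (log2 2.67), Ythdf2 (1.98) and Ythdf3 (1.97), the cytoplasmic readers, and Wtap (1.22), an adaptor of the writer complex, rose. The list of m6A readers and erasers went both ways, with 5 higher and 6 lower of 14, the same counts as when adjusted over the list alone, and did not pass (median −0.52, camera adjusted p = 0.821). Mettl14 (−0.62) and Mettl3 (−1.17) fell, with edgeR adjusted p of 0.0347 and 0.0380. Both calls were lost in at least 2 of 4 runs that left out 1 library, with adjusted p of up to 0.329 for Mettl14 and 0.125 for Mettl3. Among the m6A writers, 5 of 9 tested genes were higher and 3 lower, with the same 5 and 3 when adjusted over the list alone (median log2 1.22, camera adjusted p = 0.0145). The list had adjusted p = 0.564 with an estimated correlation, and without WT RIP replicate 1 or 2 its adjusted p was 0.0935 or 0.162. Rbm15b (log2 3.41) and Rbm15 (2.91), which bring the writer complex to its RNA targets, had the largest increases among the members named.

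Among genes of the transition to pre-B cells, 15 of 27 were higher and 6 lower, the same counts as when adjusted over the list alone (median log2 1.03, camera adjusted p = 0.0145). That list had adjusted p = 0.564 with an estimated correlation and 0.0646 without WT RIP replicate 2. Examples were Ikzf1 (log2 2.70), the tyrosine kinase Syk (2.42), the chemokine receptor Cxcr4 (2.04) and the transcription factor Klf2 (2.32). Genes of pro-B cell identity went both ways, with 12 higher and 10 lower of 28, and the same counts adjusted over the list alone. Their median was 0.12, their mean was −0.03 and the list did not pass (camera adjusted p = 0.932). Within it Cd79b rose while Cd79a, its partner in the B cell receptor, fell from 571 ± 22.4 to 36.1 ± 4.34 CPM (log2 −3.98), as did the adaptor Blnk (−2.06) and the ectoenzyme Bst1 (−2.24). Rag2 (2.22) and Rag1 (1.30), which encode the recombinase that cuts DNA at V, D and J segments, rose. The B-lineage factor Pax5 rose by less (0.74, edgeR adjusted p = 0.00911, up to 0.145 with 1 library left out). Ebf1, another B-lineage factor, had a log2 difference of 0.38 that did not pass (edgeR adjusted p = 0.0949). In IL-7 receptor and STAT5 signalling, 16 genes were higher and 8 lower of 29, or 16 and 9 adjusted over the list alone (camera adjusted p = 0.236). Pik3r1 (log2 2.62), a regulatory subunit of PI3 kinase, and Myc (2.02), a driver of proliferation, rose, while the phosphatases Ptpn2 (−2.65) and Ptpn6 (−2.16) fell.

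Further lists stood apart from other genes, each with the same counts when adjusted over the list alone. Of 65 Zfp zinc finger genes, 53 were higher and 1 lower (median log2 1.95, camera adjusted p = 3.61e-11, and adjusted p = 0.564 with an estimated correlation), with Zfp26 at 3.19 and Zfp58 at 3.50. Of 30 immediate early genes, 21 were higher and 1 lower (median 1.33, camera adjusted p = 9.77e-06, and adjusted p = 0.564 with an estimated correlation), among them Ier5 (3.09) and Tnfaip3 (2.40). Of 43 chromatin regulators, 31 were higher and 4 lower (median 1.19, camera adjusted p = 1.05e-05, and adjusted p = 0.564 with an estimated correlation). Asxl1 rose (2.88), whereas Ezh2, the H3K27 methyltransferase, fell (−2.31). Of 78 cytosolic ribosomal protein genes, 75 were lower and 0 higher (median −3.64, camera adjusted p = 5.84e-43, and adjusted p = 0.564 with an estimated correlation). Of 66 nuclear respiratory chain genes, 63 were lower and 0 higher (median −3.28, camera adjusted p = 1.01e-29, and adjusted p = 0.564 with an estimated correlation), with Cox7b at −4.59 and Atp5l at −5.04. Of 45 cell cycle genes, 28 were lower and 9 higher (median −1.07, camera adjusted p = 0.00467, and adjusted p = 0.663 with an estimated correlation), led by the thymidylate synthase gene Tyms (−3.37) and Cdk4 (−3.05). The other lists had camera adjusted p of 0.215 to 0.989.

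**Figure D1:**
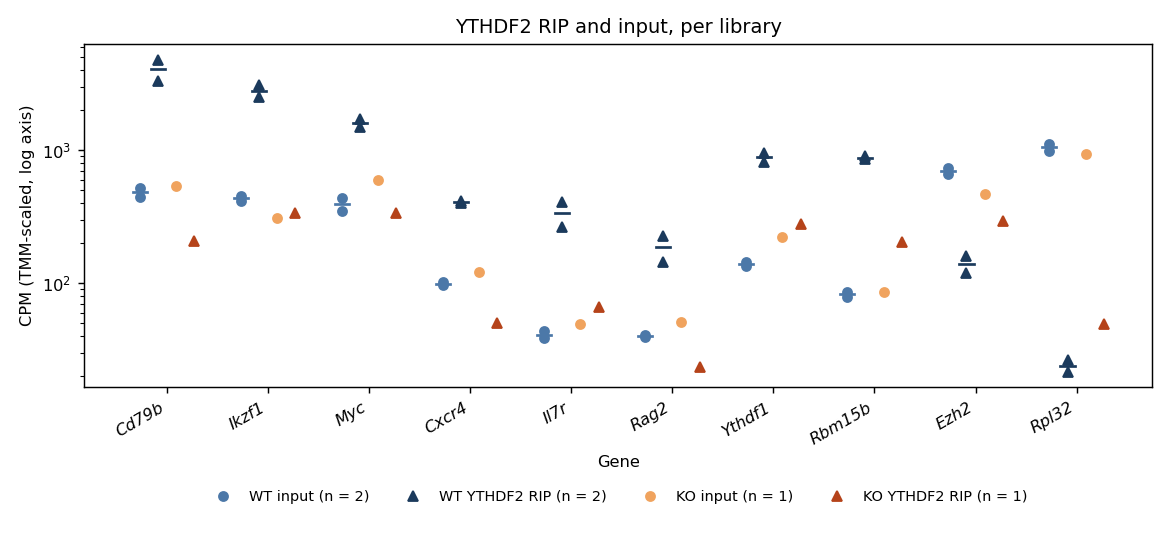
Level in CPM (log axis) of 10 genes in each of the 6 RIP-seq libraries, with points for libraries and bars at the mean of the 2 WT libraries of a kind. Cd79b averaged 483 CPM in WT input and 4065 CPM in WT RIP but read 535 CPM in KO input and 209 CPM in KO RIP, whereas Rpl32 was depleted in the RIP of both genotypes.

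These calls compare RIP with input, and no immunoprecipitation with a control antibody was analysed here, so enrichment includes whatever binds unspecifically. Reads of ribosomal protein and Zfp genes may be shared with pseudogenes and paralogs, and how reads with several matches were counted is not given in the sources used here.

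The next comparison described m6A peaks in each genotype. The WT list held 9148 peaks in 5664 gene names and the KO list 5083 peaks in 3763 gene names. The median fold enrichment over input, as the authors' peak caller gave it, was 6.84 in WT and 3.41 in KO. KO peaks overlapped 25.8% of WT peaks (Wilson 95% confidence interval 24.9 to 26.7%), and WT peaks overlapped 47.4% of KO peaks (46.0 to 48.8%). Genes with peaks in both lists numbered 2526, against 3102 with WT peaks alone and 1218 with KO peaks alone. Of 4545 genes with a WT peak and at least 10 CPM in both inputs, 50.6% had no KO peak (49.2 to 52.1%). Peaks that spanned more than 1 block of the gene model made up 17.8% of the WT list and 52.8% of the KO list.

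Several regulators of B cell growth and recombination carried WT peaks that no KO peak overlapped. All positions are on mm9, and the exon or UTR that a peak lies in was not analysed here. Myc had 3 WT peaks and 0 KO peaks, the strongest on chromosome 15 from 61821047 to 61821706 at 16.7-fold. Cd79b had a WT peak on chromosome 11 from 106172655 to 106173065 at 8.03-fold, and Cxcr4 one on chromosome 1 from 130485281 to 130485578 at 16.8-fold. Rag1 had 4 WT peaks and 0 KO peaks, the strongest on chromosome 2 from 101481968 to 101482626 at 17.8-fold. The WT peak of Rag2, from 101469734 to 101471135 on the same chromosome, had no overlap with the 2 KO peaks of that gene. Il7r kept an overlapped peak on chromosome 15, from 9436334 to 9437054 at 20.1-fold in WT and from 9436784 to 9437024 at 4.74-fold in KO. Klf2 had 2 peaks in each list, and Pax5 had 4 in WT and 2 in KO.

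The peaks chosen by the fixed rule as the most significant WT peaks without overlap, all with a p-value listed as 0, lay in Zc3h4, Mgat1, Pag1, Bcl11a, Ythdf2, Thap12, Il17ra, Zbtb14, Cdca2 and Rin3. Their folds ran from 9.90 in Il17ra to 27.7 in Thap12. The peak of Bcl11a, a transcription factor that early B cells need, lay on chromosome 11 from 24063988 to 24065277 (18.9-fold). The peak of Ythdf2 lay on chromosome 4 from 131742570 to 131761043 in 2 blocks (14.6-fold). The corresponding KO peaks lay in Myh9, Serbp1, Tpm3, Set and H2-D1, with folds of 2.90 to 5.36 and 3 to 10 blocks each. The number of peaks is a property of each list, since whether the WT replicates were pooled and which threshold was used are not given in the sources used here. No test between genotypes was possible on 1 list each.

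Transcripts with m6A peaks were compared with those without for YTHDF2 association. In WT, 5523 tested genes with a WT peak had a median log2 RIP over input of 0.89, against −0.97 in 6110 genes without any peak, a difference of 1.87. The set passed against all other genes (camera p = 1.48e-31, and p = 0.0143 with an estimated correlation) and, in a test added after the results were seen, against genes without peaks alone (p = 8.42e-29 at the preset correlation and p = 0.0156 with an estimated correlation). Of the genes with a WT peak, 55.9% were higher in RIP and 14.9% lower, against 8.09% and 43.0% of genes without peaks. The median rose with the number of WT peaks, from −1.05 with 0 and 0.46 with 1 to 1.29 with 2, 1.60 with 3 and 1.91 with 4 or more. The median transcript length implied by counts and FPKM rose along the same classes, from 2.89 to 8.78 kb. With genes without peaks matched on length, the difference was 1.94.

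**Figure D2:**
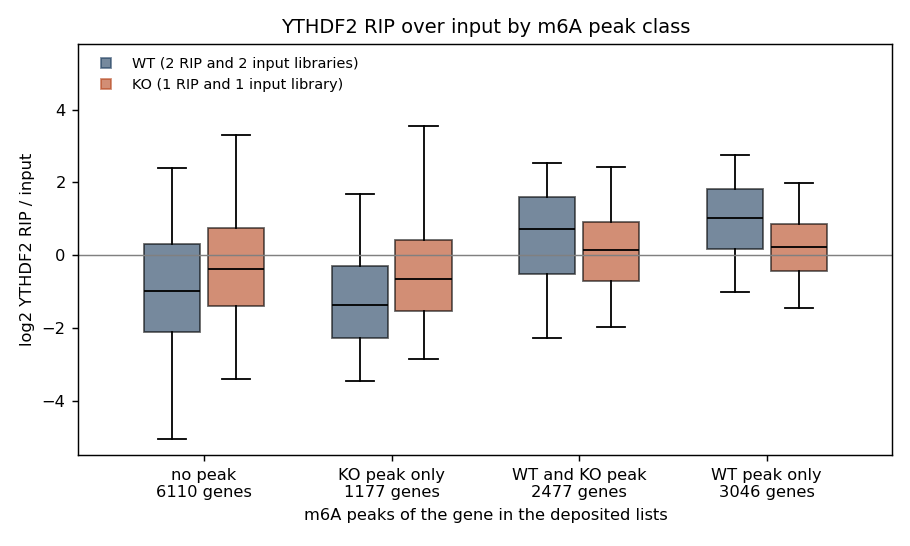
Log2 RIP over input in WT and in KO for 6110 genes without peaks, 1177 with KO peaks alone, 2477 with peaks in both lists and 3046 with WT peaks alone. Boxes span the quartiles with the median inside and whiskers run from percentile 5 to 95. Genes with WT peaks alone had a median of 1.01 in WT and 0.21 in KO, and genes without peaks −0.97 and −0.40.

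The following comparison asked whether YTHDF2 association differed without Mettl14. Most genes called lower in KO had been enriched in WT RIP and carried a WT m6A peak, among them Cd79b, Myc, Rag2 and Il7r. Cd79b read 4065 ± 1047 CPM in WT RIP (SD, n = 2) and 209 CPM in KO RIP, while both genotypes held it at similar input levels, 483 ± 54.0 and 535 CPM. Its KO minus WT difference in log2 RIP over input was −4.43 (SE 0.40, edgeR adjusted p = 0.0122). Myc fell by 2.84, Rag2 by 3.34, Il7r by 2.60, Ythdf1 by 2.35, Wtap by 1.96 and Ythdf2 by 1.73 on the same scale, with edgeR adjusted p of 0.0132 to 0.0267. Across 12810 genes, the difference was called higher in 816 and lower in 1279. Of the 1279 lower genes, 1190 (93.0%) had a WT peak and 1149 (89.8%) were higher in WT RIP, whereas 203 of the 816 higher genes (24.9%) had a WT peak, against 43.1% of all genes tested. The WT ratio enters both the enrichment and the difference, so part of their relation arises by construction. The difference did not pass for Rag1 (−0.90, edgeR adjusted p = 0.108), Ythdf3 (−0.77), Pax5 (−0.32), Ebf1 (−0.29), Mettl14 (−0.75) or Mettl3 (0.80).

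The genes with the largest decreases by the fixed rule were Rnase12 (−4.84), B3gnt8 (−4.47), Cd79b (−4.43), Tnfaip8l1 (−4.36), AA414768 (−4.19), Nxt1 (−4.11), AI467606 (−4.05), Gimap7 (−4.02), Cxcr5 (−3.91) and Nrros (−3.89). Nxt1 encodes a factor of mRNA export and Cxcr5 a chemokine receptor that guides B cells to follicles. The largest increases were in Acadsb (4.16), Met (3.32), Srxn1 (3.31), Mmp19 (3.22), Aoc3 (3.16), Medag (3.15), Fgf7 (3.14), Dlc1 (3.13), Gpx8 (3.12) and Sod3 (3.10). Met encodes the receptor of hepatocyte growth factor, Fgf7 a growth factor made by mesenchymal cells and Mmp19 a matrix metalloproteinase. Fgf7 read 21.1 ± 2.21 CPM in WT RIP (SD, n = 2) and 242 CPM in KO RIP, and its inputs read 19.2 ± 2.79 and 24.9 CPM. Stromal and megakaryocyte markers were high in the same KO RIP library, with a median difference of 2.01 over 10 genes (camera adjusted p = 0.00419, and adjusted p = 0.663 with an estimated correlation). Of these, 3 were called higher and 0 lower, or 5 and 0 adjusted over the list alone. Vcam1 (2.35), Pdgfrb (1.94) and Sparc (2.09) passed.

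Lists of pro-B and pre-B cell genes were lower in this difference. Mature B cell markers did not pass (median 0.71, camera adjusted p = 0.799), with 0 higher and 1 lower of 12 over all genes and adjusted over the list alone. WT peaks lay in 19 of 28 pro-B, 15 of 27 pre-B and 2 of 14 mature B cell genes counted. They also lay in 7 of 9 m6A writers, 51 of 66 Zfp genes and 21 of 30 immediate early genes. All tested genes with a WT peak had a median of −0.56. Each list was tested against all other genes, so a fall particular to B cell stage genes was not shown. Among pro-B cell identity genes, 13 of 28 were lower and 2 higher, or 14 and 6 adjusted over the list alone (median −0.68, camera adjusted p = 0.00188, and adjusted p = 0.666 with an estimated correlation). Igll1 (−2.26) and Vpreb2 (−2.45), which encode surrogate light chain components, were among them. Among genes of the pre-B cell transition, 9 of 27 were lower and 1 higher, or 10 and 2 adjusted over the list alone (median −0.90, camera adjusted p = 5.23e-04, and adjusted p = 0.663 with an estimated correlation). Examples were Cxcr4 (−3.30), the inhibitory receptor Cd22 (−2.80), Ikzf1 (−2.58) and Klf2 (−2.63). Of 9 m6A writers, 4 were lower and 0 higher, or 5 and 0 adjusted over the list alone (median −0.93, camera adjusted p = 0.00188, and adjusted p = 0.663 with an estimated correlation), namely Rbm15b (−2.18), Rbm15 (−2.42), Zc3h13 (−1.74) and Wtap (−1.96). Of 65 Zfp genes, 11 were lower and 0 higher, or 16 and 0 adjusted over the list alone (median −1.06, camera adjusted p = 6.26e-04, and adjusted p = 0.691 with an estimated correlation). Of 30 immediate early genes, 5 were lower and 0 higher, or 6 and 0 adjusted over the list alone (median −0.38, camera adjusted p = 0.0335, and adjusted p = 0.666 with an estimated correlation), led by Jund (−3.01). That list had adjusted p of 0.0539 without WT input replicate 1 and 0.147 without WT RIP replicate 2. IL-7 receptor and STAT5 genes, with 7 of 29 lower and 1 higher, or 10 and 5 adjusted over the list alone, did not pass as a list (camera adjusted p = 0.0510), though Socs2 (−2.31) and Cish (−2.48), feedback inhibitors of cytokine signalling, fell.

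Ribosomal protein and respiratory chain lists, depleted in WT RIP, had positive medians in this difference, though most of their members did not pass. Genes without peaks had a higher median, 0.72, and 6.53% of them were called higher. Few members of the lists had a WT peak (2 of 79 and 3 of 67). Each list was tested against all other genes, including peak genes that fell, so its positive median is not particular to it. Of 78 ribosomal protein genes, 5 were called higher and 0 lower, or 1 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 0.00191, and adjusted p = 0.691 with an estimated correlation), for example Fau (2.25) and Rpl10 (1.42). Of 66 respiratory chain genes, 7 were higher and 0 lower, or 5 and 0 adjusted over the list alone (median 0.54, camera adjusted p = 0.00526, and adjusted p = 0.691 with an estimated correlation), for example Ndufa9 (1.59) and Atp5b (1.28). The respiratory chain list had adjusted p = 0.0529 without WT RIP replicate 2. Ezh2 (1.64) and the splicing regulator Hnrnpa2b1 (1.64) also rose in this difference.

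**Figure D3:**
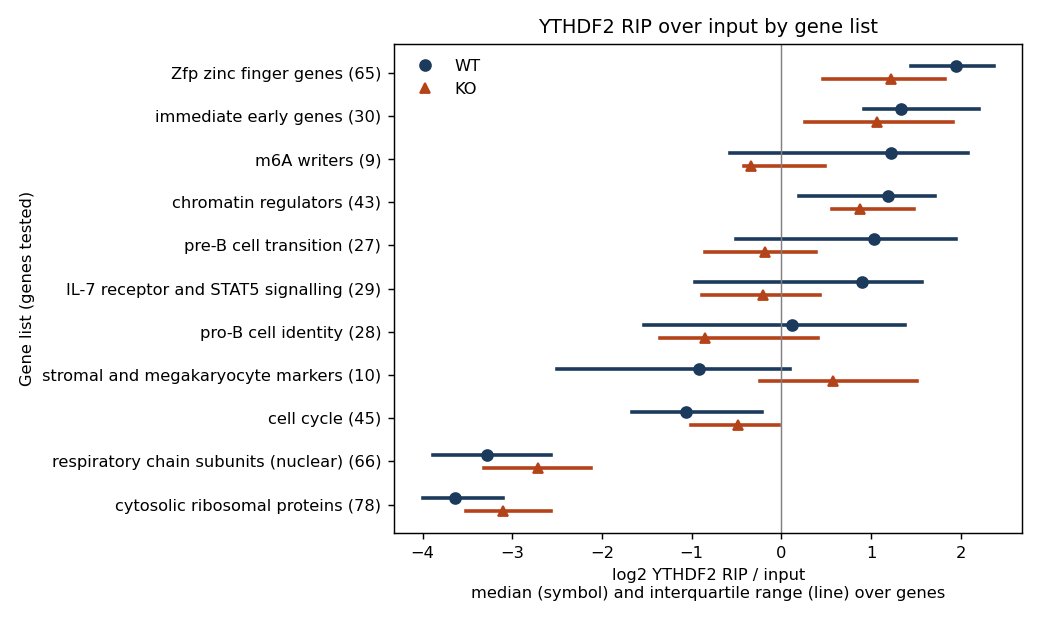
Median and quartiles over genes of log2 RIP over input for 11 gene lists in WT and in KO. Ribosomal protein genes had a median of −3.64 in WT and −3.10 in KO, and pre-B cell transition genes 1.03 in WT and −0.18 in KO.

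Within the KO, values alone can be given. RIP exceeded KO input by at least 2-fold in 2738 genes and fell at least 2-fold below it in 3340, against 3710 and 4336 in WT. Genes called higher in WT RIP had a median log2 ratio of 1.65 in WT and 0.65 in KO, where 75.3% kept the sign. Genes called lower had −1.91 and −1.11, where 86.2% kept it. Across genes, which are not independent replicates, the KO log2 ratio had a slope of 0.47 on the WT ratio (Pearson r = 0.547). Both gene sets were chosen by their WT ratios, so smaller KO medians arise in part from that choice. Noise in the WT ratio likewise lowers the slope.

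The size of this set depended on single libraries, because the spread comes from the 2 WT pairs alone and the RIP pair varied more than the input pair. Higher and lower genes numbered 29 and 265 without WT input replicate 1, 4 and 81 without WT input replicate 2, 3615 and 3093 without WT RIP replicate 1, and 3701 and 2902 without WT RIP replicate 2. Of the 20 genes named by the rule, 13 and 11 passed without WT input replicate 1 and 2, and all 20 passed without either RIP. Of 59 other genes called and followed in lists or by name, 19 and 7 passed without those inputs. Myc, Rag2, Cxcr4, Cd22, Jund, Birc5 and Ccr7 among the 59 passed in all 4 runs, as did Cd79b among the 20. Scaling by library totals alone moved the median of all genes from 0.20 to 0.35 here and from −0.05 to 0.09 in the inputs, and the share of calls that were higher from 39.0% to 49.6%.

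By peak class, genes with WT peaks alone had a median KO minus WT difference 1.42 below that of genes without peaks (3046 genes), and genes with peaks in both lists lay 1.06 below (2477 genes). All 5523 genes with WT peaks lay 1.28 below, and genes with KO peaks alone lay 0.15 above (1177 genes). Within KO, the median RIP over input of genes with WT peaks still lay 0.58 above that of genes without peaks, against 1.87 in WT. The planned test set each class against all other genes, with peaks or without. In it, genes with WT peaks alone had camera p = 3.84e-19 (p = 0.00728 with an estimated correlation), those with peaks in both lists camera p = 4.18e-06 (p = 0.218 with an estimated correlation) and all genes with WT peaks camera p = 1.62e-24 (p = 0.0183 with an estimated correlation). Against genes without peaks alone, a test added after the results were seen, p at the preset correlation was 5.07e-34, 3.88e-16 and 9.96e-22 for these 3 sets and 1.90e-05 for genes with KO peaks alone. With an estimated correlation these were 0.00395, 0.0878, 0.0207 and 0.00499. Against all other genes, those with KO peaks alone had camera p = 4.57e-13 (p = 0.00163 with an estimated correlation). Of them, 18.2% were called higher and 1.27% lower, against 6.53% and 1.21% of genes without peaks.

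The last comparison asked how transcript levels differed in the inputs. B cell genes changed in both directions: Kit, Dntt and Rag1 were higher in KO and Ms4a1 and Cd79a lower, while the list of pro-B identity genes did not pass as a whole. Kit, the stem cell factor receptor, read 19.0 ± 0.493 CPM in WT input (SD, n = 2) and 63.9 CPM in KO input (log2 1.75, SE 0.21, edgeR adjusted p = 0.0356). Dntt, the terminal transferase of V(D)J joining, read 211 ± 12.0 and 690 CPM (log2 1.71), and Rag1 46.7 ± 6.17 and 176 CPM (log2 1.92, edgeR adjusted p = 0.0345). Ms4a1, which encodes CD20, fell from 126 ± 33.2 to 4.60 CPM (log2 −4.77, SE 0.39, edgeR adjusted p = 0.0185), and Cd79a from 571 ± 22.4 to 169 CPM (log2 −1.76). In all, 89 genes were higher and 85 lower in KO input.

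The largest increases by the fixed rule were in Ctse (4.28), Nlrx1 (3.82), Slfn2 (3.74), Ltb (3.62), Arhgef10l (3.19), P2rx7 (3.07), Ubxn11 (3.04), Spsb4 (2.98), Sestd1 (2.95) and Nfam1 (2.95). Ctse encodes cathepsin E, Ltb lymphotoxin beta and P2rx7 an ATP-gated channel. The largest decreases were in Rasgrp1 (−5.55), Ms4a1 (−4.77), Cd180 (−4.48), Fv1 (−4.44), Slfn10-ps (−4.22), Lipg (−4.04), Efnb2 (−4.01), 9930111J21Rik1 (−3.99), Zbtb8a (−3.96) and Fcrla (−3.46). Rasgrp1 encodes an activator of Ras and Cd180 a receptor of B cells. Outside B cell genes, the transcription factor gene Jund rose (1.39). Il7r (0.26), Myc (0.59), Ebf1 (0.01), Pax5 (−0.68), Rag2 (0.35), Wtap (0.71), Ythdf1 (0.68), Ythdf2 (1.17) and Ythdf3 (0.32) did not pass.

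**Figure D4:**
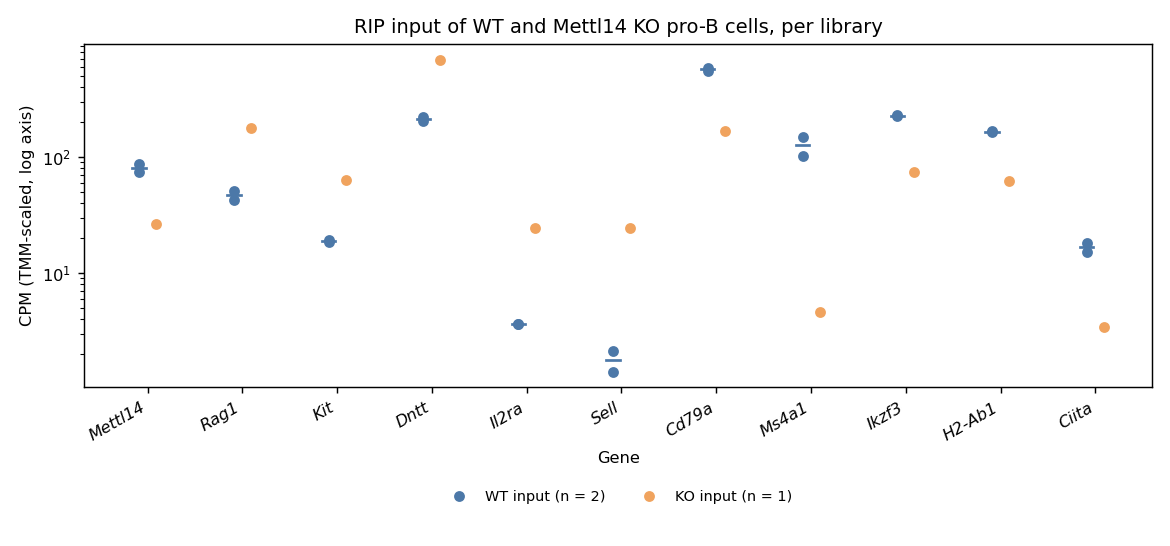
Level in CPM (log axis) of 11 genes in the 2 WT input libraries and the KO input library, with 1 point per library. Kit read 63.9 CPM in KO against a WT mean of 19.0 CPM, and Ms4a1 4.60 CPM against 126 CPM.

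Cell cycle genes were lower as a group in KO input (median −0.60 over 45 genes, camera adjusted p = 7.84e-09, and adjusted p = 0.486 with an estimated correlation). Only E2f2 (−1.55) of them was called, and 2 were lower adjusted over the list alone. Of 12 mature B cell markers, 3 were lower and 1 higher, or 6 and 3 adjusted over the list alone (median −1.32, camera adjusted p = 0.0193, and adjusted p = 0.486 with an estimated correlation). They were Ms4a1, Ciita (−2.29), the activator of MHC class II genes, and H2-Ab1 (−1.40), with L-selectin (Sell, 3.77) on the higher side. Of 27 pre-B transition genes, 3 were lower and 2 higher, or 10 and 2 adjusted over the list alone (median −0.44, camera adjusted p = 0.0193, and adjusted p = 0.486 with an estimated correlation), with the IL-2 receptor chain Il2ra (2.74) and Rag1 higher and Ms4a1 and the transcription factor Ikzf3 (−1.61) among the lower. In the pro-B identity list, 3 of 28 genes were higher and 2 lower, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.560).

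Some lists of markers of other cell types passed at the preset correlation, with few genes called. Those of NK and innate lymphoid cells and of T cells did not pass (camera adjusted p = 0.107 and 0.808). Myeloid markers had a median of 1.44 over 7 genes and stromal and megakaryocyte markers 0.62 over 10. Each had camera adjusted p = 0.0366 (adjusted p = 0.486 with an estimated correlation) and 0 genes called by edgeR over all genes or adjusted over the list alone. Of 21 myeloid markers counted, 0 reached 10 CPM in both inputs, so their median rests on low counts. Of 11 dendritic cell markers, 1 was lower, or 5 adjusted over the list alone; their median was −0.18 and their mean 0.07 (camera adjusted p = 0.0476, and adjusted p = 0.486 with an estimated correlation). CCR4-NOT and decay factors had a median of −0.26 and ribosomal protein genes of −0.21, each with camera adjusted p = 0.0366 (adjusted p = 0.486 and 0.775 with an estimated correlation). Of their 34 and 78 genes, 0 were called over all genes or adjusted over the list alone. Zfp genes had a median of −0.26 (camera adjusted p = 0.0476, and adjusted p = 0.831 with an estimated correlation), and 5 were lower adjusted over the list alone. Over scaling and leave-one-out runs, the adjusted p of the lists called in the inputs ran from 1.10e-09 to 0.165, and 2 of 9 passed in all.

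These counts rested on few libraries. Higher and lower genes numbered 9 and 19 without WT input replicate 1, 3 and 11 without WT input replicate 2, 1708 and 1533 without WT RIP replicate 1, and 1709 and 2072 without WT RIP replicate 2, which supply the spread although they are not compared. Of the 20 genes named by the rule, 13 and 8 passed without WT input replicate 1 and 2. Of 11 further called genes, which include Kit, Dntt, Rag1 and Cd79a, 0 passed edgeR without either input, with adjusted p of 0.0873 to 0.467, and on all libraries DESeq2 called 11, limma on FPKM 0 (adjusted p of 0.0653 to 0.121) and edgeR with no count filter 0 (0.120 to 0.138). Scaling by library totals moved the share of calls that were higher from 51.1% to 67.4%.

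Input differences of transcripts with WT m6A peaks passed under some settings only. Genes with WT peaks alone had a median KO minus WT difference 0.07 above that of genes without peaks, and genes with peaks in both lists 0.09 above. Against all other genes they had camera p = 0.451 and 0.247 (p = 0.436 and 0.699 with an estimated correlation), and against genes without peaks alone p = 0.358 and 0.191 at the preset correlation and p = 0.360 and 0.664 with an estimated correlation. For genes with KO peaks alone the difference was −0.06. Against all other genes this class had camera p = 0.0442 (p = 0.0205 with an estimated correlation), or 0.0590 and 0.0351 adjusted over the 12 tests of that kind. Against genes without peaks, camera p was 0.0845 at the preset correlation and 0.0296 with an estimated correlation. Adjusted over the 12 tests of peak sets against genes without peaks, a step added after the results were seen, these were 0.113 and 0.0507, and every other set kept its side of 0.05 under each. Against genes without peaks matched on mean CPM, the differences of the first 2 sets passed at the preset correlation, at 0.15 (p = 0.0326) and 0.25 (p = 1.32e-04), as they did matched on implied length, at 0.14 and 0.15 (p = 0.0440 and 0.0219).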

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

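The 4 tests on stromal genes were chosen only after the result was seen, and so was the use of implied length as an alternative setting. Each result in this paragraph drew attention because the interaction term found a difference between KO and WT in RIP over input. Of the genes tested, 816 were higher and 1279 lower in KO. Among genes chosen by the naming rule, the log2 difference was 4.16 for Acadsb, 3.32 for Met, 3.31 for Srxn1, 3.22 for Mmp19, 3.16 for Aoc3, 3.15 for Medag, 3.14 for Fgf7, 3.13 for Dlc1, 3.12 for Gpx8 and 3.10 for Sod3. It was −4.84 for Rnase12, −4.47 for B3gnt8, −4.43 for Cd79b, −4.36 for Tnfaip8l1, −4.19 for AA414768, −4.11 for Nxt1, −4.05 for AI467606, −4.02 for Gimap7, −3.91 for Cxcr5 and −3.89 for Nrros. Among regulators chosen in advance it was −1.96 for Wtap, −2.35 for Ythdf1, −1.73 for Ythdf2, −2.60 for Il7r, −3.34 for Rag2 and −2.84 for Myc. List medians were 0.52 for ribosomal proteins, 0.54 for the respiratory chain, 2.01 for stromal markers, −0.38 for immediate early genes, −0.93 for m6A writers, −0.90 for the pre-B transition, −0.68 for pro-B identity and −1.06 for Zfp genes. Relative to genes without peaks, the median difference was −1.28 for genes with WT peaks, −1.42 with WT peaks alone, −1.06 with peaks in both lists and 0.15 with KO peaks alone.

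Genes with WT peaks were higher in WT RIP over input. Longer transcripts have more room for peaks, and abundant ones more reads to call them. With genes without peaks matched on implied length, the median difference was 1.94 (95% interval over resampled genes 1.88 to 2.03, 3332 genes per side). Matched on mean CPM over all libraries it was 2.11 (2.01 to 2.19, 3084 per side). The first value argues against length as the whole cause. The second cannot settle expression level, because that mean includes the RIP libraries whose enrichment is compared. An association of YTHDF2 with methylated transcripts is consistent with these values as a hypothesis, and unspecific recovery stays open because no control immunoprecipitation was analysed here.

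Genes with WT peaks were lower in KO than in WT. If a weaker immunoprecipitation in the KO library shrank all ratios alike, peak genes and others of the same WT ratio would have the same KO ratio. The KO ratio of peak genes differed from that of such genes by a median of −0.37 (−0.45 to −0.28, 3229 genes per side). Matched on implied length, the KO minus WT difference was −1.43 (−1.48 to −1.36). These values argue against uniform shrinkage or length as the whole cause. A weaker immunoprecipitation that recovered more unspecific RNA stays open, because it could lower peak genes more than others of the same WT ratio. It could account for part of the slope below 1 between the KO and WT ratios, as could noise in the WT ratio. Knockout of Mettl14 is the difference that the design names. As each KO fraction had 1 library, a difference peculiar to that library stays open.

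Stromal genes were high in the KO RIP library, where Cxcl12 read 641 CPM (133 and 62.7 in WT RIP), Col1a2 719 CPM (170 and 77.2) and Pdgfrb 151 CPM (29.8 and 20.2). Their median KO minus WT difference was 2.57 in RIP (2.17 to 2.71) but 0.62 in input (0.56 to 0.99), where Cxcl12 read 462 CPM against 283 and 336. Transcripts of stromal marker genes were thus present in the inputs of both genotypes, and which cells they came from was not tested. More stromal RNA in the KO cell sample would leave most of the larger RIP difference unaccounted for. If a weaker immunoprecipitation drew all ratios toward 0 alike, the list would keep the KO ratios of genes with its WT ratios. Yet its median ratio went from −0.92 in WT to 0.58 in KO, and 7 of its 10 genes crossed 0 or moved away from it. Its KO ratios lay a median of 1.28 (0.87 to 1.72) above those of genes with the same WT ratio (percentile 99.35 of 10000 random lists matched on that ratio). The list was picked for its high difference, which the interval and the percentile in part restate. These values therefore describe the list and cannot test uniform shrinkage. A weaker immunoprecipitation that recovered more unspecific RNA was not tested by them, because the random lists were not matched on peaks or length. Genes without peaks also had a positive median difference, 0.72. RNA from another source in the RIP library stays open, though not as a matter of that library alone, since the input difference lies above 0, and no biological explanation was tested.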

How the results depend on the processing

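Length matching, testing peak sets against genes without peaks alone, and leaving out 351 genes found mainly in KO RIP, were chosen after seeing the data; every alternative chosen in advance was run. The WT RIP against input counts stayed within 1.5 times, and of the genes called by both limma on FPKM and edgeR there, 7310 of 7311 had the same sign; all calls shared with other alternatives kept it. Of gene values beyond single-library runs, 2465 kept their side of the threshold, 87 gained and 130 lost it; with 1 library left out these were 1014, 180 and 174. Without those 351 genes, 2053 of the 2095 interaction calls were shared (98.0%). No filter tests 15934 genes in place of 12810, and leaving out a library leaves the spread to 1 fuller pair. The causes of the changes below were not tested.

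In the interaction, 816 higher genes became 68 with no filter, 1598 by DESeq2 and 1305 by limma on FPKM; 1279 lower became 404 with no filter. In KO input, 89 higher genes became 0 with no filter, 193 with at least 50 counts, 373 by DESeq2 and 2 by limma; 85 lower became 0, 417 by DESeq2 and 5 by limma. Beside edgeR's 0 calls with no filter, 2044 genes had an unadjusted p under 0.05. With 1 library left out, the interaction ranged from 4 to 3701 higher and 81 to 3093 lower, and KO input from 3 to 1709 higher and 11 to 2072 lower.

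The titles give WT RIP libraries and their inputs the same replicate numbers, but whether equal numbers mean the same cells is not stated. The deviations of RIP and input between replicates had a correlation of 0.0392 over 10967 genes. With 2 pairs, this value cannot settle whether the libraries are paired. With a replicate block, the interaction had 1622 higher genes and KO input 443 higher and 386 lower.

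Genes with peaks in both lists kept their interaction difference of −1.06 with an estimated correlation but lost the call (p = 0.218), also against genes without peaks alone (p = 0.0878 with an estimated correlation). In the inputs, genes with WT peaks alone passed when matched on CPM (0.15) or length (0.14), and genes with peaks in both lists with library totals at the preset correlation (0.10, p = 0.0411) or matched on CPM (0.25) or length (0.15). The overlapped share of WT peaks (25.8%) was 22.8% in the better-scoring part of the lists, 17.9% with a larger overlap required, 50.5% by gene name and 26.9% at 10 CPM or more; the KO share (47.4%) was 41.0%, 39.7% and 72.4% under the first 3 of these. Depth limits genes of few counts, and small interaction differences were rarely recovered in simulation.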

Other observations

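The genes in this part were chosen after their values were seen, except list members. Mat2a, which encodes the enzyme that makes the methyl donor S-adenosylmethionine, held the largest share of the KO RIP library, 285121 counts or 1.12% of its total. It read 9678 CPM in KO RIP, 2148 and 2849 CPM in WT RIP, 189 CPM in KO input and 229 and 252 CPM in WT input. The KO minus WT difference was 2.30 (SE 0.33, edgeR adjusted p = 0.0155), so that Mat2a moved against most transcripts that were enriched in WT RIP. D17H6S56E-5 went the other way in input, at 936 and 889 CPM in WT and 88.0 CPM in KO (log2 −3.37, edgeR adjusted p = 0.0185), and read 8124 and 9280 CPM in WT RIP against 114 CPM in KO RIP.

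Decay factors and other regulators also differed between RIP and input. In WT, Ddx6, a helicase of P-bodies, rose, as did the deadenylase adaptor Tob1 (log2 2.11), while the nuclear exonuclease Xrn2 fell (−2.46). In the interaction, Xrn2 (1.61) and Cnot1 (1.64), the scaffold of the CCR4-NOT complex, rose and Upf2 (−1.53), a factor of nonsense-mediated decay, fell; each of these 3 calls passed in 2 of 4 runs with 1 library left out. The list of decay factors passed neither test (camera adjusted p = 0.865 in WT RIP and 0.334 in the interaction). Among plasma cell markers, the transcription factor gene Xbp1 rose in WT RIP (2.34) and fell in the interaction (−2.58), and the list did not pass (camera adjusted p = 0.0789). Of cell cycle genes, Birc5, which encodes survivin, fell in the interaction (−3.07) and read 319 ± 1.28 CPM in WT RIP (SD, n = 2) against 34.5 CPM in KO RIP, whereas the list, with 7 higher and 4 lower of 45, or 10 and 4 adjusted over the list alone, had a median of 0.67 and did not pass (camera adjusted p = 0.192).

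Across 10271 genes, which are not independent replicates, implied length had a Spearman rho of 0.407 with the WT log2 RIP over input and of 0.659 with the KO ratio. Peaks without overlap spanned more than 1 block in 10.2% of the WT list and 65.0% of the KO list.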
